A study of Rattus norvegicus with 6 samples.

How the data were processed

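Gene expression was measured on single-colour Affymetrix arrays of primary hippocampal neurons of rat embryos (day 18), infected at 4 days in vitro with adeno-associated virus carrying a control or an Ncoa3 shRNA and harvested at 14 days in vitro. RNA was extracted with the mirVana kit, per the labels' protocols. The deposited table holds 1 log2 signal per probe set and array, and the values range from about 2 to 14. The authors processed the arrays with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation method, the normalization and the genome build are not given in the sources used here. The labels describe the samples of a group as separate experiments, numbered 1 to 3, so each group holds 3 replicates and each experiment gave 1 array per group.

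The deposited values show that the arrays of each group share a processing step that the other group does not. The highest signal was 14.05 on all control shRNA arrays and 14.00 on all Ncoa3 shRNA arrays. Between 8680 and 13979 of the 36685 probe sets had identical values on a pair of arrays of the same group, against 0 to 2 on a pair of different groups. On all 3 arrays of a group, 7154 probe sets (19.5%) were identical with control shRNA and 7265 (19.8%) with Ncoa3 shRNA. The array medians differed by -0.28 (Ncoa3 shRNA minus control; exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 arrays can give). The difference in median gene signal shrank from -0.29 in the dimmest to -0.14 in the brightest of 10 bins of genes. Shared values may make the spread between replicates smaller than that of separately measured signals, and error between separate runs would fall wholly between the groups. The adjusted p-values describe these values and leave out such error.

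Probe sets were named through the platform's annotation table, which can be old. It listed 19086 of 36685 probe sets, of which 18511 have 1 gene symbol and 575 several, and 17599 probe sets carried no symbol and are unnamed here. Of the symbols, 18394 were found in the RefSeq gene table (assembly GRCr8) and 0 were changed by it. No coordinates were used, since the build behind the annotation is not given in the sources used here. For the 291 genes with several probe sets, the one with the highest mean over the 6 arrays was used, which left 18166 genes. Control probe sets could not be told from other unnamed probe sets, so the difference between 3' and 5' ends of transcripts was not computed. Of the 568 entries in the gene lists, 499 were measured. Some listed genes, including members of the microRNA list, were not on a probe set with a single symbol and are not reported here.

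Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean signal), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The main test used the deposited values of all 6 arrays without a block. A second count took genes that also differed by at least 1.5-fold. The labels say that a number marks a shared experiment, so the same fit with the experiment as a block is given where it alters a call or moves a count by over 1.5 times. Deviations from the group means correlated between the arrays of the same experiment at r = 0.75, 0.56 and 0.80 over genes, which are not independent replicates. Between arrays of different experiments the correlations were -0.76 to 0.54. For each gene the deviations of a group sum to 0, so positive correlations within experiments force negative ones between some. The first principal component held 58.1% of the variance and parted the groups, and the second held 33.0% and set both arrays of experiment 3 apart.

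Because the groups differed in median signal, changes in the report come from a fit of the same kind after quantile normalization of all 6 arrays. Quantile normalization removes any true change common to most genes. Where a gene had the same deposited value on all arrays of each group, its later spread within a group comes from the normalization alone. A signal-matched distance was added after the data were seen: a gene's deposited difference minus the median of the 500 genes nearest in mean signal, divided by their robust SD. It describes these arrays and has no p-value.

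Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and with camera at an estimated correlation and with fry beside it. Camera asks whether a list's genes moved more than other genes, and fry whether they moved one way on balance. For each list the number of members past the threshold was also counted adjusted over the list alone. The lists were miRNA biogenesis and RISC, nuclear receptor coregulators, nuclear receptors, glucocorticoid-responsive genes, IGF and PI3K-Akt signalling, activity-regulated genes, excitatory postsynapse, presynapse and vesicle release, GABAergic neurons and inhibitory synapse, dendrite and spine cytoskeleton, voltage-gated ion channels, circadian clock, cholesterol synthesis, oxidative phosphorylation, interferon response, p53 response, unfolded protein and integrated stress response, heat shock and RNA-handling stress, cell cycle, and markers of astrocytes, microglia, the oligodendrocyte lineage, endothelial and mural cells, and fibroblasts and meninges.

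The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Ncoa3, the Argonaute genes and Dicer1 whatever their p, and the members of the microRNA and coregulator lists past the threshold in the deposited values. It then named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with the same sign in all 3 experiments and a mean above the median of all genes, passing over symbols that are only locus identifiers. Last came up to 4 members with the smallest p from each list past camera's test, and the 2 brightest members of each other cell type or stress list.

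The alternatives chosen in advance were the block, a filter on genes dimmer than the median, the mean of a gene's probe sets, no trend in the variance prior, quantile normalization, equal array medians, array weights, all probe sets, each array or experiment left out, the block with the filter, an estimated correlation and fry. Cyclic loess normalization, the block with quantile normalization, with equal array medians or with cyclic loess, quantile normalization without experiment 3, and a restriction to the 5654 genes with no identical values within a group were added after the data were seen. The procedure was tested on simulated data of 18166 genes made as 1 joint run, with 200 genes changed. It recovered 46% of genes changed by a log2 of 0.5 and 65% of those changed by 1, with 0 of wrong sign and 6 false calls. A list of 25 genes shifted by 0.3 was found, and 0 of 23 other lists were called. The noise was drawn independently for each gene. The simulation therefore does not test lists whose genes vary together, such as the microRNA list with an estimated correlation of 0.66. All 6 arrays were used.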

Results

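RNA was measured on 6 arrays of primary rat hippocampal neurons, taken from embryos at day 18 and grown with 10 µM FUDR, a nucleoside analogue that stops dividing cells from growing in such cultures. The neurons were infected at 4 days in vitro with adeno-associated virus, at 1800000 infectious units per ml, that carried either a control short hairpin RNA (shRNA) or an shRNA against Ncoa3, and RNA was taken at 14 days in vitro. Ncoa3 is a coactivator that nuclear receptors recruit to switch genes on. There were 3 control shRNA arrays and 3 Ncoa3 shRNA arrays, with 1 array of each kind in each of 3 experiments. The comparison asks how expression in these neurons differed once Ncoa3 was silenced. The deposited log2 signals had a mean array median of 7.15 ± 0.0899 (SD, n = 3) with control shRNA and 6.86 ± 0.0910 (SD, n = 3) with Ncoa3 shRNA, and 18166 genes were tested. The number of arrays limits the precision.

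Ncoa3 was lower in the Ncoa3 shRNA arrays in all 3 experiments. Its deposited log2 signal was 8.68 ± 0.274 (SD, n = 3) with control shRNA and 7.41 ± 0.0201 (SD, n = 3) with Ncoa3 shRNA, on its only probe set (17769041), a difference of -1.26. After all 6 arrays were given the same distribution of signal (quantile normalization), the change was -0.97 ± 0.142 (SE, n = 3 per group), or 1.96-fold lower, with limma's adjusted p = 0.00747. The change by experiment was -1.03, -1.12 and -0.77. The deposited value of Ncoa3 was the same with Ncoa3 shRNA in experiments 1 and 2, which may make the SD there too small. Without experiment 1, the adjusted p in the deposited values rose from 0.00224 to 0.0636.

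Among the genes brighter than the median, Cyb5r3, Map9 and Cnot6 had larger mean falls than Ncoa3 itself. In experiment 2 Cnot6 fell by less than Ncoa3 after quantile normalization (-1.10 against -1.12), and no test compared these genes. The median difference over all genes was -0.25 in the deposited values, so changes are given relative to that offset, from the quantile-normalized signals, unless called deposited. Cyb5r3, the gene of NADH-cytochrome b5 reductase (probe set 17839557), fell the furthest of these genes. Its deposited signal was 12.79 ± 0.139 with control shRNA and 10.42 ± 0.379 with Ncoa3 shRNA (SD, n = 3 each), and relative to the offset it was 4.64-fold lower, a log2 change of -2.21 ± 0.204 (SE; limma's adjusted p = 0.00170). Map9, which encodes a microtubule-associated protein (probe set 17739321), was 3.18-fold lower at -1.67 ± 0.102 (SE; adjusted p = 6.00e-04), and Cnot6, a deadenylase subunit of the CCR4-NOT complex that shortens mRNA tails (probe set 17655807), was 2.21-fold lower at -1.15 ± 0.0636 (SE; adjusted p = 5.33e-04). Each of these 3 genes was lower in all 3 experiments, as the rule for naming them required of the deposited values. The deposited value of Map9 was the same on all 3 control arrays. With Ncoa3 shRNA, Map9 and Cnot6 each had the same deposited value in experiments 1 and 2, which may make their SEs too small.

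**Figure D1:**
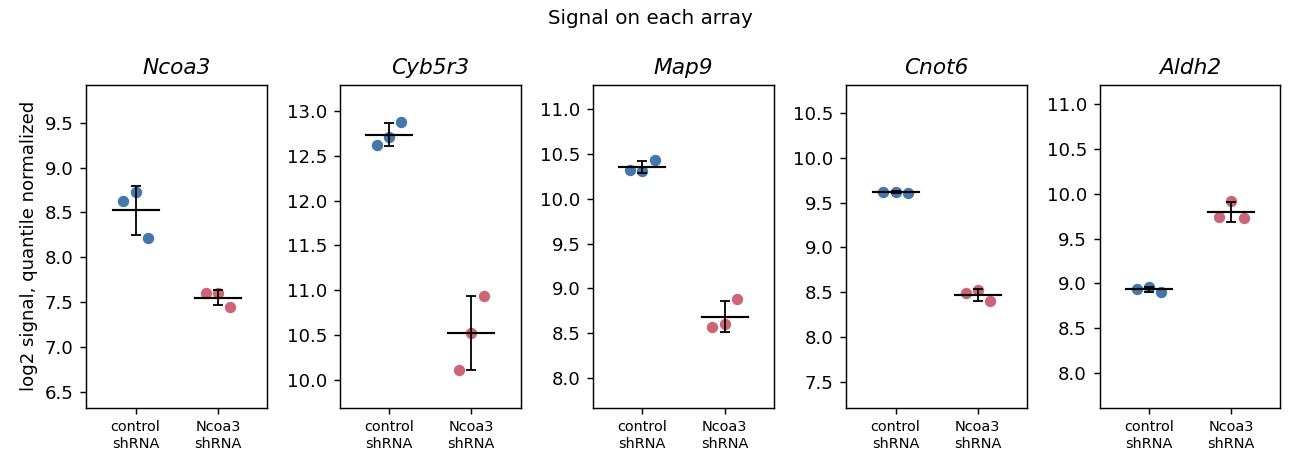
Log2 signal after quantile normalization (vertical axis, each panel spanning the same range) of Ncoa3, Cyb5r3, Map9, Cnot6 and Aldh2 on the 3 control shRNA arrays (blue) and the 3 Ncoa3 shRNA arrays (red); points are arrays, ordered by experiment, and black lines are the mean and SD of 3 arrays. The groups do not overlap in any panel, with mean differences of -0.97, -2.21, -1.67, -1.15 and 0.86.

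The next genes in order of the deposited fall were Nek7, Tia1, Spast, Gdap1, Cast and Secisbp2l. Nek7, a NIMA-related kinase, changed by -0.95, Tia1, an RNA-binding protein of stress granules, by -0.87, and Spast, the microtubule-severing ATPase spastin, by -0.87. Gdap1, a protein of the mitochondrial outer membrane, changed by -0.84, Cast, the calpain inhibitor calpastatin, by -0.79, and Secisbp2l by -0.82. These 6 genes were lower in all 3 experiments, which the same rule required, with limma's adjusted p between 0.00340 for Spast and 0.0221 for Gdap1. The calls of Tia1, Spast, Gdap1 and Cast in the deposited values were lost without experiment 1, and those of Tia1, Spast and Cast also without experiment 2 (adjusted p up to 0.112, 0.0531, 0.108 and 0.115).

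The largest of the named rises was smaller than the falls of Cyb5r3, Map9 and Cnot6. Aldh2, the mitochondrial aldehyde dehydrogenase, rose the most among the 10 genes named for their rise, 1.82-fold or 0.86 ± 0.0763 (SE, n = 3 per group; limma's adjusted p = 0.00156). It was followed by Tmod4, a tropomodulin that caps actin filaments, at 0.78, Mrto4, a ribosome assembly factor, at 0.72, and the extracellular matrix gene Fn1 (fibronectin) at 0.65. The potassium channel gene Kcnk12 changed by 0.62, Gpx4, a glutathione peroxidase that protects membrane lipids, by 0.60, Tmem44 by 0.60, Sdr39u1 by 0.58, Selenom by 0.57 and Nppc, the precursor of C-type natriuretic peptide, by 0.56. All 10 were higher in each experiment, as the rule for naming them required of the deposited values. Their adjusted p in limma's test ran from 9.43e-04 for Nppc to 0.0125 for Selenom. Of the 9 fits of the deposited values that left out 1 array or experiment, 7 lost the call of Selenom (adjusted p up to 0.289), 7 that of Gpx4 (0.154) and 4 that of Tmem44 (0.153), and without experiment 1 the calls of Tmod4 (0.105), Aldh2 (0.0841) and Sdr39u1 (0.0548) were lost, that of Tmod4 without experiment 2 as well. The deposited value of Fn1 was the same on all 3 arrays of each group, so its experiments could not disagree in sign there, and that of Kcnk12 was the same on all 3 control arrays. Of the genes brighter than the median, 2 lay above and 14 below the 500 genes nearest in signal by at least 4 robust SDs, each of them on the same side in all 3 experiments. Those above were Aldh2 and Slc18a3, the gene of the vesicular acetylcholine transporter, at 0.87 (adjusted p = 0.0242), which was chosen after its values were seen.

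With the deposited values, 8579 of the 18166 genes passed limma's test at an adjusted p of 0.05, of which 722 were higher and 7857 lower, and 1387 of them differed by at least 1.5-fold (34 higher, 1353 lower). Relative to the offset 3548 genes (19.5%) passed, 1905 higher and 1643 lower, of which 211 higher and 192 lower by at least 1.5-fold. With the experiment as a block, 7147 genes (39.3%) passed (3777 higher and 3370 lower). The counts of the lists below are to be read against these shares, and against 47.2% in the deposited values. The control and the Ncoa3 shRNA arrays appear to have been summarised in separate runs, so run and group cannot be told apart and the p-values leave out the error between runs. Of 1344 olfactory and vomeronasal receptor genes, whose median signal was 4.82, 491 passed as well (245 higher, 246 lower).

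**Figure D2:**
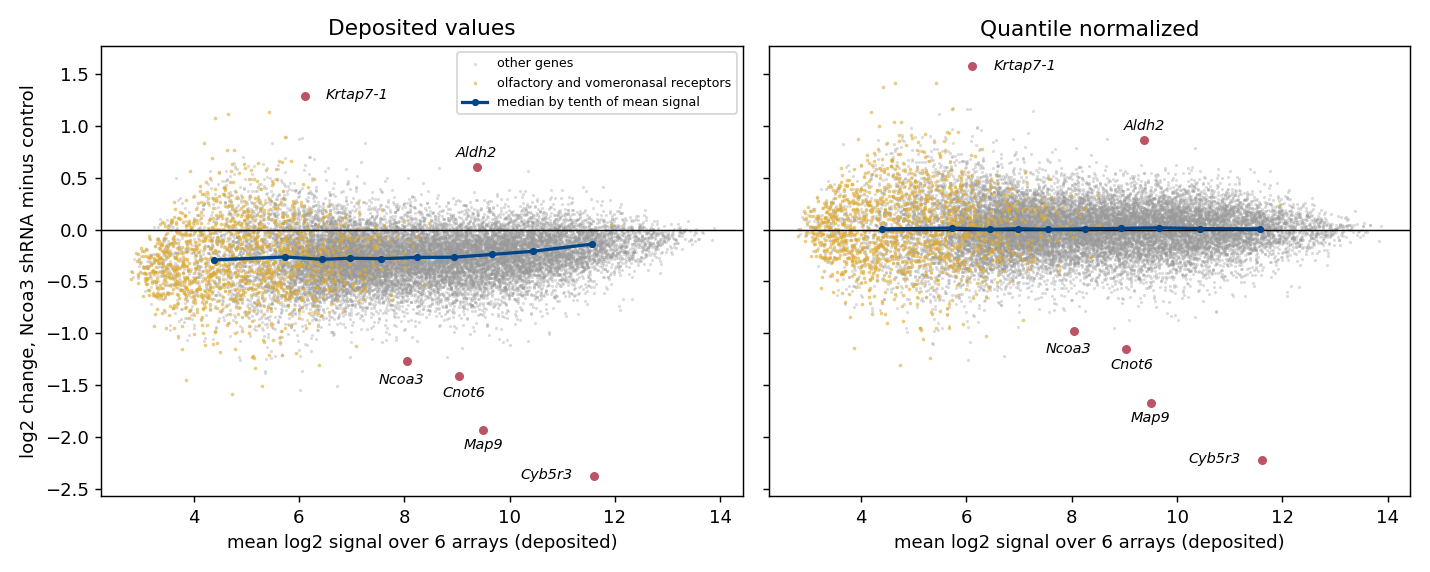
Log2 change, Ncoa3 shRNA minus control shRNA (vertical axis), against the mean deposited log2 signal over 6 arrays (horizontal axis) for 18166 genes, with the deposited values on the left and quantile-normalized values on the right; orange points are olfactory and vomeronasal receptor genes, the blue line is the median in each of 10 bins of genes by signal, and red points are named genes. The median runs from -0.29 in the dimmest bin to -0.14 in the brightest on the left and lies near 0 on the right, while Cyb5r3 at -2.21, Map9 at -1.67 and Cnot6 at -1.15 lie below the other genes of their signal.

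Of the 20 measured genes of the microRNA pathway, 2 fell and 0 rose, where 19.5% of all genes passed in either direction. Ddx6, a helicase of mRNA decay, changed by -0.62 (adjusted p = 0.0176) and Ddx5, a helicase partner of the microRNA processor Drosha, by -0.54 (adjusted p = 0.00373). The Argonaute gene Ago1, whose product binds microRNAs, stood at 10.47 ± 0.207 with control shRNA and 9.93 ± 0.202 with Ncoa3 shRNA in the deposited values (SD, n = 3 each). Its change relative to the offset was -0.31 ± 0.109 (SE), which did not pass limma's test (adjusted p = 0.104) but did with the experiment as a block (adjusted p = 0.0101). Ago3 stood at -0.27 (adjusted p = 0.160), Ago4 at -0.04 (adjusted p = 0.862), and Tnrc6a, a scaffold of the silencing complex, at -0.20 (adjusted p = 0.248, and 0.0249 with the block). Dicer1, the microRNA-processing enzyme, stood at -0.23 in the deposited values and at 0.03 relative to the offset (adjusted p = 0.790). The same pair of values was -0.16 and 0.10 for Tnrc6b and -0.25 and -0.05 for Cnot1, and neither passed relative to the offset. Of the 20 measured genes of this list 2 fell, 0 rose and 18 did not pass, with 2 falls adjusted over the list alone, and 2 rose and 6 fell with the experiment as a block. Of the deposited values 9 were lower and 0 higher (16 and 0 with the block), 6 of any direction adjusted over the list alone, and there the call of Ddx6 was lost without experiment 1 or 2 (adjusted p up to 0.145). Of the 9 fits there that left out 1 array or experiment, 7 lost the call of Ago1 (limma's adjusted p up to 0.225), 7 that of Ago4 (0.188) and 6 that of Tnrc6a (0.268). The calls of Ago3 and Cnot1 were lost in 2 each and that of Tnrc6b in 1. The list was not past camera's test with the deposited values (adjusted p = 0.822) or after quantile normalization (0.359).

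Among nuclear receptor coregulators, the family to which Ncoa3 belongs, Ncoa7 changed by -0.58 (adjusted p = 0.0114) and Tbl1xr1, a subunit of the corepressor complexes, by -0.43 (adjusted p = 0.0336). The corepressor Ncor1 stood at -0.25 (adjusted p = 0.0610, and 0.0277 with the block), Ncoa1 at -0.15 (0.0815, and 0.0355 with the block) and the acetyltransferase gene Kat2b at -0.20 (0.137, and 0.00847 with the block). These 3 genes had shared deposited values too. Those of Ncor1 and Ncoa1 were the same on control shRNA replicates 1 and 2. That of Kat2b was the same on control shRNA replicates 1 and 3 and on Ncoa3 shRNA replicates 1 and 2. Ncoa4 stood at -0.14, Ncoa5 at -0.07, Nrip1 at -0.13, Ppargc1a at -0.18 (adjusted p = 0.0388 with the block) and Med1 at 0.03, none of them past limma's test. Of 17 measured members other than Ncoa3, 1 rose, 2 fell and 14 did not pass, the same counts as adjusted over the list alone (1 and 2), while 1 rose and 6 fell with the block. In the deposited values 10 were lower and 0 higher (10 adjusted over the list alone), and there the call of Tbl1xr1 was lost without experiment 1 (adjusted p = 0.0738) and that of Ncoa7 without experiment 2 (0.0846). Of the 9 fits there that left out 1 array or experiment, 8 lost the call of Nrip1 (limma's adjusted p up to 0.143) and 7 that of Med1 (0.181). The call of Ncoa5 was lost in 4, that of Ppargc1a in 3 and that of Ncoa4 in 2. Camera gave an adjusted p of 0.822 with the deposited values and 0.359 after quantile normalization.

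Genes that neuronal activity switches on were, as a list, higher than other genes in the deposited values. Dusp1, a phosphatase of MAP kinases, rose by 0.49 relative to the offset (limma's adjusted p = 0.0145), and Fos, chosen after its values were seen like Nr4a1, rose by 0.47 (0.0168). The orphan nuclear receptor gene Nr4a1 rose by 0.43 (0.0383). The kinase gene Plk2 went the other way, at -0.30 (0.0436), while Junb at 0.17 (0.136, and 0.0317 with the block) and Klf4 at 0.00 (0.973) did not pass. Both stood below 0 in the deposited values, at -0.10 and -0.28, with the same value on all 3 arrays of each group. Their spread within a group after quantile normalization therefore came from the normalization alone. Of 29 measured members 5 rose, 1 fell and 23 did not pass, and 5 rose and 1 fell adjusted over the list alone. With the block 15 rose and 1 fell. In the deposited values 1 was higher and 4 lower (4 and 7 with the block), 3 of any direction adjusted over the list alone, and 4 of the 9 fits with 1 array or experiment left out lost the call of Dusp1 (adjusted p up to 0.146) and 1 that of Plk2 (0.0689, without experiment 2). The list was past camera's test in the deposited values as higher than other genes (adjusted p = 0.0144), although the list's median there was -0.08. The call was lost with an estimated correlation (adjusted p = 0.616) and after quantile normalization (adjusted p = 0.125), where the experiment as a block gave an adjusted p of 0.0117. It was also lost in the deposited values without Ncoa3 shRNA replicate 3 (0.102) and without experiment 1 (0.0505).

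Cell cycle genes were lower as a list in the deposited values. Cenpf, a kinetochore protein gene, changed by -0.40 relative to the offset (limma's adjusted p = 0.0119). Kif20a at -0.23, the cyclin gene Ccna2 at -0.17 and the proliferation marker Mki67 at -0.11 did not pass, while all 4 passed in the deposited values, with differences of -0.68, -0.51, -0.46 and -0.39 and the same value on all 3 arrays of each group. With the block Kif20a, Ccna2 and Mki67 passed at adjusted p = 0.00588, 0.00961 and 0.0214. The spread of all 4 genes within a group came from the normalization alone. Their p-values after it therefore do not measure variation between replicates. All 4 genes were dimmer than the median gene (7.89), with deposited means under control shRNA from 6.18 for Mki67 to 6.91 for Kif20a. Of 24 measured members 3 rose, 3 fell and 18 did not pass, with 3 and 3 adjusted over the list alone, and 7 rose and 12 fell with the block. In the deposited values 3 were higher and 18 lower (22 adjusted over the list alone), and 1 and 19 with the block. Camera's adjusted p was 0.0330 in the deposited values, 0.534 with an estimated correlation and 0.698 after quantile normalization, and with the block it was 0.141 in the deposited values. The call was lost there without control shRNA replicate 3 (0.0850), Ncoa3 shRNA replicate 3 (0.102), experiment 1 (0.0505) or experiment 3 (0.379).

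Synapse and channel genes moved in both directions. The 4 genes named here were chosen after their values were seen. Of 20 measured genes of GABAergic neurons and the inhibitory synapse, 3 rose and 3 fell, and 4 and 3 did so adjusted over the list alone. The inhibitory transmitter transporter gene Slc32a1 rose by 0.50 (limma's adjusted p = 0.0122), and Gad2, the gene of a GABA-synthesising enzyme, changed by -0.42 (0.0349). Of 27 genes of the presynapse and vesicle release 0 rose and 2 fell by either adjustment, which were Vamp1 at -0.69 and Amph at -0.34, and 1 rose and 3 fell with the block. Of 28 genes of the excitatory postsynapse 1 rose and 0 fell (0 adjusted over the list alone), and 2 rose and 4 fell with the block. Of 29 voltage-gated ion channel genes 3 rose and 0 fell (0 adjusted over the list alone), and 6 rose and 3 fell with the block. Of 24 dendrite and spine cytoskeleton genes 0 passed limma's test by either adjustment and 1 rose with the block. With the deposited values 2 GABAergic genes were higher and 5 lower, and in the other 4 lists 0 were higher, with 13 lower for the presynapse, 9 for the postsynapse, 10 for ion channels and 10 for dendrites and spines. With the block 2 were higher and 9 lower of the GABAergic genes and 1 and 14 of the ion channels. Camera's adjusted p with the deposited values was 0.101 for the GABAergic list, 0.822 for the presynapse, 0.822 for the postsynapse, 0.788 for ion channels and 0.822 for dendrites and spines, and after quantile normalization 0.928, 0.708, 0.912, 0.912 and 0.912.

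Lists of receptors, signalling and metabolism did not pass camera's test, though single members passed limma's. The orphan receptor gene Esrrg rose by 0.58, Ppard by 0.55 and the clock gene Per1 by 0.48, while Rorb changed by -0.53, with limma's adjusted p from 0.00215 to 0.00667. These 4 genes were chosen after their values were seen, and the deposited value of Per1 was the same on all 3 arrays of each group, as were those of Esrrg and Rorb on all 3 Ncoa3 shRNA arrays. Of 30 nuclear receptor genes 5 rose and 2 fell, 5 and 3 adjusted over the list alone, and 7 rose and 5 fell with the block. Of 14 glucocorticoid-responsive genes 3 rose and 0 fell by either adjustment. Of 17 circadian clock genes 1 rose and 1 fell by either adjustment, and 4 rose and 2 fell with the block. Of 20 genes of IGF and PI3K-Akt signalling 2 rose and 0 fell (1 adjusted over the list alone), and 5 rose and 3 fell with the block. Of 29 genes of oxidative phosphorylation 1 rose and 5 fell by either adjustment, and 2 rose and 5 fell with the block. Of 19 genes of cholesterol synthesis 0 passed limma's test by either adjustment, and 1 rose and 1 fell with the block. The deposited values had 2 higher and 12 lower among the nuclear receptors, 3 and 4 among the glucocorticoid-responsive genes, 1 and 5 for the clock, 1 and 7 for IGF signalling, 0 and 6 for oxidative phosphorylation and 0 and 6 for cholesterol synthesis. With the block these became 3 and 7 for the glucocorticoid-responsive genes, 1 and 8 for the clock, 1 and 12 for IGF signalling and 0 and 11 for oxidative phosphorylation. Camera's adjusted p with those values was 0.788 for nuclear receptors, 0.101 for glucocorticoid-responsive genes, 0.552 for the clock, 0.813 for IGF signalling, 0.446 for oxidative phosphorylation and 0.813 for cholesterol synthesis, and after quantile normalization 0.708, 0.359, 0.996, 0.996, 0.996 and 0.825.

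Markers of other cell types moved in both directions, and the balance of rises and falls turned with the scaling for those of microglia, fibroblasts, the oligodendrocyte lineage and endothelial and mural cells. Of 20 microglia markers 7 rose and 1 fell, 8 and 2 adjusted over the list alone, and 11 rose and 3 fell with the block. The 2 brightest of them were Lyz2 at 0.21 (limma's adjusted p = 0.650, and 0.0193 with the block) and C1qa at 0.12 (0.304). Of 15 fibroblast and meningeal markers 3 rose and 1 fell by either adjustment, and 7 rose and 3 fell with the block, with Fn1 at 0.65 and the matrix gene Dcn at 0.52 (0.0385). Of 16 oligodendrocyte lineage markers 4 rose and 2 fell by either adjustment, with Cnp at 0.41 (0.0300) and the myelin gene Mbp at 0.09 (0.434). Of 12 endothelial and mural markers 3 rose and 1 fell by either adjustment, and 4 rose and 3 fell with the block, with Tagln at 0.31 (0.0472) and Rgs5 at 0.08 (0.411). Of 17 astrocyte markers 0 rose and 1 fell (0 adjusted over the list alone), and 2 rose and 3 fell with the block, with Vim at 0.10 (0.121) and Aldoc at 0.09 (0.887). The deposited values of these markers gave other counts, as 3 were higher and 5 lower for microglia, 1 and 8 for fibroblasts, 3 and 7 for oligodendrocytes, 2 and 6 for endothelial and mural cells and 0 and 5 for astrocytes, and with the block 2 and 8 for fibroblasts and 0 and 8 for astrocytes. Camera's adjusted p with those values was 0.0579 for microglia, 0.822 for fibroblasts, 0.576 for oligodendrocytes, 0.822 for endothelial and mural cells and 0.788 for astrocytes, and after quantile normalization 0.145, 0.350, 0.708, 0.716 and 0.928. Lyz2, C1qa, Mbp, Rgs5 and Aldoc lay below 0 in the deposited values, at -0.07, -0.17, -0.19, -0.20 and -0.03.

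Stress response lists did not pass camera's test either. Of 24 interferon response genes 7 rose and 4 fell, 8 and 6 adjusted over the list alone, and 10 rose and 6 fell with the block, with Stat2 at 0.04 and Irf9 at -0.03. Of 23 genes of the unfolded protein and integrated stress response 3 rose and 0 fell by either adjustment, and 5 rose and 1 fell with the block, with Calr and Hspa5 both at 0.02. Of 16 p53 response genes 3 rose and 0 fell by either adjustment, and 4 rose and 1 fell with the block, with Plk3 at 0.46 (limma's adjusted p = 0.0458) and Ccng1 at -0.01. Of 9 genes of heat shock and RNA-handling stress 1 rose and 0 fell, 1 and 1 adjusted over the list alone, and 1 rose and 2 fell with the block, with Hspa8 at -0.02 and Dnaja1 at -0.15 (adjusted p = 0.0516, and 0.0451 with the block). More genes of each list were lower than higher in the deposited values, with 5 higher and 13 lower for the interferon response, 1 and 2 for the unfolded protein response, 1 and 5 for p53 and 0 and 5 for heat shock, and with the block 1 and 8 for the unfolded protein response and 1 and 8 for p53. Camera's adjusted p with those values was 0.822 for the interferon response, 0.203 for the unfolded protein response, 0.637 for p53 and 0.822 for heat shock, and after quantile normalization 0.698, 0.359, 0.716 and 0.928. For 18 of the 24 lists the median deposited change was below 0 although camera put the list above other genes. After quantile normalization the median, the mean and camera's direction differed in sign for IGF signalling, oxidative phosphorylation, astrocyte markers and heat shock.

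**Figure D3:**
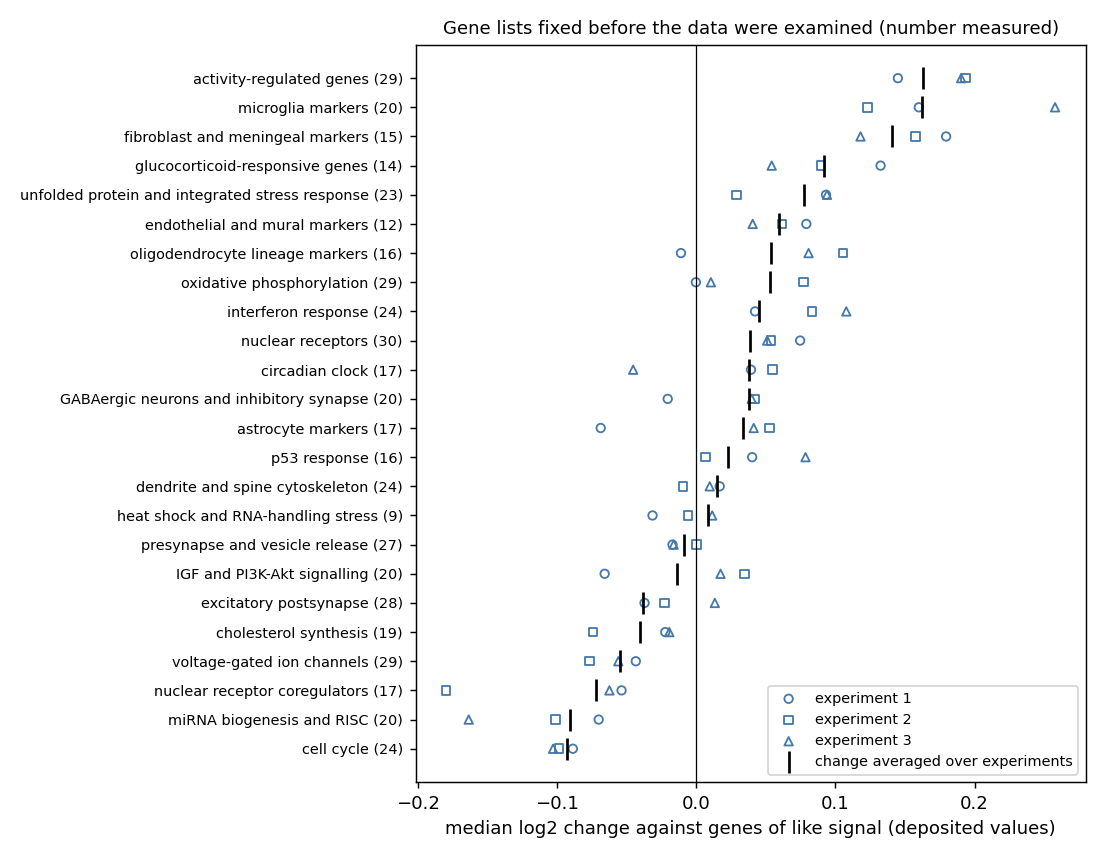
Median log2 change of the genes of each of 24 lists, relative to genes of like signal (horizontal axis, deposited values), in each of 3 experiments (open symbols) and for the change averaged over experiments (black bars); the number of measured genes stands in brackets. Activity-regulated genes lie at 0.14, 0.19 and 0.19 in the 3 experiments, microglia markers at 0.16, 0.12 and 0.26, and cell cycle genes at -0.09, -0.10 and -0.10.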

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

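The count of splits and its test were planned. The other tests in this part were chosen after the results were seen.

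Cyb5r3, Map9 and Cnot6 had larger mean falls than the gene that the shRNA targets, with changes of -2.21, -1.67 and -1.15 against -0.97 for Ncoa3. They lay 14.6, 8.17 and 5.64 robust SDs below genes of like signal, and Ncoa3 4.78. In experiment 2 Cnot6 fell by less than Ncoa3 (-1.10 against -1.12), and no test compared these genes. Among 121 genes with 2 probe sets brighter than the median gene, the changes of the 2 differed by 0.74 at most. The falls of Cyb5r3 and Map9 exceed 1.5 times that difference (1.11) by more than 2 SEs. Both were picked as the largest falls among all genes brighter than the median, and the SEs leave out error between runs. Noise of single probe sets between separate runs is therefore not excluded for either of them. The change of Cnot6 lies within 2 SEs of the limit of 1.11, and that of Ncoa3 (-0.97) lies inside it. Such noise cannot be told apart from a real fall for these 2 genes. Silencing of further transcripts by the Ncoa3 shRNA, and a fall that follows from the loss of Ncoa3, may each account for the falls of Cyb5r3, Map9 and Cnot6. They were not tested, as the shRNA sequence was not used here.

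The threshold was passed by 8579 genes in the deposited values, 91.6% of them lower. An offset between separate processing runs would also shift genes that hippocampal neurons are not known to use. The olfactory and vomeronasal receptor genes, taken as such genes, had a median deposited difference of -0.30. This fits an offset and leaves open whether a common fall adds to it. Noise of probe sets between runs could account for many of the calls that are left, since 36.5% of the receptor genes passed after quantile normalization, against 18.2% of the other genes. Replicate spread made too small by shared values stays open, since 0.195% of the genes with no identical values within a group passed, against 47.2% of all genes, but with the experiment as a block 56.8% of them passed, against 60.2% of all genes, and such genes are by construction the more variable ones. The real grouping called those 8579 genes, 1387 of them beyond 1.5-fold. The highest of the other 9 of the 10 splits called 0 of either kind (1 split of 10 as large for each count). All of those 9 splits mix the groups, which puts any difference between runs into the replicate spread. Their counts of 0 genes therefore cannot tell a real effect from separate processing. For the lists, 2 passed in the real grouping and 9 of 10 splits gave as many, with 9 lists in the highest. The 10 splits are too few for a share under 0.05.

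The genes with no identical values within a group that passed in the deposited values, chosen after their values were seen, were Cyb5r3, Ddx5, Nek7, Dusp18, Enc1, Rab2a, Secisbp2l, Cacybp, Bbof1, Or6c211 and LOC689246, 11 of 5654 and all of them lower, in values that carry a median difference of -0.24 over those genes. Or6c211, with a quantile-normalized change of -0.88, is itself an olfactory receptor gene, of the kind that these neurons are not known to use. After quantile normalization 1 of the 5654 passed, and with the experiment as a block as well 428 passed as higher and 462 as lower.

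Among the 6432 probe sets without a single gene symbol that were brighter than the median probe set, 1 had a deposited difference at least 4 robust SDs above those of like signal and 8 as far below. The results above name none of these probe sets, which entered the count over all probe sets alone. The one farthest below those of like signal, at -6.48 robust SDs, stood at 8.53 with control shRNA and 6.86 with Ncoa3 shRNA in the deposited values (17609663), a quantile-normalized change of -1.38, and the next, at -6.41, went from 8.26 to 6.52 (17602735), a larger change of -1.45.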

How the results depend on the processing

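Cyclic loess, the block with quantile normalization, equal array medians or cyclic loess, quantile normalization without experiment 3 and the restriction to genes without identical values were chosen after the results were seen, and the other alternatives were planned. The fall of Ncoa3 kept its direction in the 21 alternatives run for it, at -1.42 to -0.97, and passed in 20 of them. It was not among the genes without identical values, and all probe sets and the block with the filter were run for counts only. Without experiment 1 it was -1.21 with an adjusted p of 0.0636 (range 2.25e-05 to 0.0636), a fit with 4 arrays. The share of lower genes among those called fell from 91.6% to 46.3% with quantile normalization, which removes the offset between the groups. No signal over background came with the arrays, so dim genes could not be set apart from unexpressed ones. Values were already on the log2 scale, so no pseudocount was varied, and the gene lists were not run without the variance trend. The cause of the differences below was not tested. In some alternatives fewer genes or arrays entered the fit, and whether that accounts for their counts was not tested either.

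With the deposited values 8579 genes passed (722 higher, 7857 lower), 1387 beyond 1.5-fold, and 2 lists. After quantile normalization 3548 passed (1905 higher, 1643 lower), 403 beyond 1.5-fold and 0 lists (3 at an unadjusted p under 0.05 in camera). With equal array medians 1868 passed (841 lower), 408 beyond 1.5-fold and 1 list. With cyclic loess 4622 passed (2437 higher, 2185 lower), 412 beyond 1.5-fold and 0 lists. With array weights, whose estimation stopped before convergence, 13147 passed (1197 higher, 11950 lower) and 1 list. The filter on dim genes, which tests fewer genes, left 2412 (77 higher, 2335 lower) and 351 beyond 1.5-fold, and glucocorticoid-responsive genes then passed camera. All probe sets gave 15385 (1301 higher, 14084 lower). Only genes without identical values gave 11 (0 higher, 11 lower), all 11 beyond 1.5-fold, and 1 list. The replicate block alone gave 10932 genes and 1 list. The replicate block with the filter gave 5035 (161 higher, 4874 lower), with quantile normalization 7147 (3777 higher, 3370 lower), 459 beyond 1.5-fold and 1 list, with equal array medians 7892 (4746 higher, 3146 lower), 466 beyond 1.5-fold and 1 list, and with cyclic loess 7156 (3716 higher, 3440 lower), 464 beyond 1.5-fold and 1 list. In the deposited values the block ended the calls of Ago4, Nrip1, Selenom, Gpx4 and the cell cycle list (adjusted p = 0.0623, 0.0851, 0.0579, 0.0705 and 0.141) and added Lyz2 and Dcn (0.0176 and 0.00527), and it changed no other call of a named gene or list there. Quantile normalization without experiment 3 gave 8354 (4436 higher, 3918 lower), 555 beyond 1.5-fold and 0 lists. An estimated correlation left 0 lists. Leaving out 1 array or experiment gave 5133 to 11098 genes (480 to 1067 higher, 4653 to 10031 lower), 885 to 1701 beyond 1.5-fold and 0 to 3 lists, with Ncoa3 at -1.42 to -1.16. The lowest counts of genes came without experiment 1 and the highest without experiment 3. No list passed without Ncoa3 shRNA replicate 3 or without experiment 1.

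Some named genes were lower in the deposited values and higher in others. After quantile normalization the changes were Dicer1 0.027, Tnrc6b 0.10, Med1 0.029, Klf4 0.0040, Junb 0.17, Stat2 0.036, Calr 0.021, Hspa5 0.022, Aldoc 0.088, Lyz2 0.21, C1qa 0.12, Mbp 0.088 and Rgs5 0.079, and the replicate block with quantile normalization gave the same changes, of which Lyz2 and Junb then passed. With equal array medians they were Dicer1 0.054, Tnrc6b 0.12, Cnot1 0.035, Med1 0.12, Klf4 0.0067, Junb 0.18, Stat2 0.060, Ccng1 0.13, Calr 0.20, Hspa5 0.20, Aldoc 0.25, Lyz2 0.22, C1qa 0.11, Mbp 0.093, Rgs5 0.078, Hspa8 0.19 and Dnaja1 0.030. The replicate block with equal array medians gave the same changes, and Junb, Calr, Hspa5, Aldoc, Lyz2 and Hspa8 then passed. With cyclic loess they were Dicer1 0.0060, Tnrc6b 0.078, Med1 0.010, Klf4 0.0014, Junb 0.15, Stat2 0.023, Calr 0.028, Hspa5 0.032, Aldoc 0.087, Lyz2 0.20, C1qa 0.11, Mbp 0.065 and Rgs5 0.076, the same with the replicate block, where Junb and Lyz2 passed. After quantile normalization without experiment 3 they were Ago4 0.066, Dicer1 0.017, Tnrc6b 0.088, Med1 0.029, Klf4 0.0093, Junb 0.18, Stat2 0.079, Calr 0.018, Hspa5 0.015, Aldoc 0.12, Lyz2 0.22, C1qa 0.031, Mbp 0.091 and Rgs5 0.12. Of these, Junb, Lyz2 and Rgs5 passed. Array weights turned Aldoc to 0.20 and Vim to -0.0055. With 1 array or experiment left out, Vim ranged from -0.030 to 0.021 (-0.029 without control shRNA replicate 2, where it passed), Aldoc from -0.29 to 0.24, Lyz2 from -0.28 to 0.14 and Tagln from -0.029 to 0.13, and no other named gene changed sign. Of the 52 named genes that passed with all arrays in the deposited values, 29 no longer passed without experiment 1, 20 without experiment 2, 8 without experiment 3 and 5 to 9 without a single array.

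Fry tests against no change instead of against other genes, and called 23 lists in the deposited values and 4 after quantile normalization. Of its lists that lay above other genes in camera, glucocorticoid-responsive genes were called as higher by fry too, with a mean deposited change of -0.077, and the others were called as lower, with mean deposited changes as follows: nuclear receptors -0.22, IGF and PI3K-Akt signalling -0.24, activity-regulated genes -0.070, excitatory postsynapse -0.26, GABAergic neurons and inhibitory synapse -0.18, dendrite and spine cytoskeleton -0.19, voltage-gated ion channels -0.25, cholesterol synthesis -0.19, oxidative phosphorylation -0.18, interferon response -0.23, p53 response -0.19, unfolded protein and integrated stress response -0.14, astrocyte markers -0.22, microglia markers -0.075, oligodendrocyte lineage markers -0.19 and fibroblast and meningeal markers -0.12.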

Other observations

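The tests on activity-regulated genes and on gene families in this part were chosen after the results were seen.

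Selenoprotein genes, which encode enzymes that carry selenocysteine, were mostly higher than genes of like signal. Of 24 measured, 17 lay above and 7 below, with a median change of 0.10 relative to the offset, and Gpx4 at 0.60 and Selenom at 0.57 were among the 4 that rose (1 fell), while 8 rose and 2 fell with the experiment as a block. Histone genes were also mostly higher, 29 of 41 lying above genes of like signal with a median of 0.13, and 6 rose and 0 fell in limma's test (11 and 2 with the block). Genes of ribosomal proteins lay higher in 37 of 52 cases, with a median of 0.08. Genes of RNA-binding proteins (DEAD-box helicases, hnRNP, Srsf, Sf3 and Rbm families) lay lower in 74 of 105 cases, with a median of -0.10, and Ddx5 at -0.54 was among the 10 that fell, while 4 rose (24 and 10 with the block). After quantile normalization none of these 4 families passed camera over the 8 families looked at, with adjusted p of 0.0694, 0.0573, 0.0694 and 0.0573 in the order given and unadjusted p of 0.0422, 0.0143, 0.0434 and 0.00830. With the deposited values selenoproteins (adjusted p = 0.00507) and histones (0.0124) passed as higher than other genes, and ribosomal (0.0944) and RNA-binding proteins (0.605) did not. In the deposited values the medians of selenoprotein, histone, ribosomal and RNA-binding protein genes lay below 0, at -0.14, -0.04, -0.10 and -0.35, and camera's direction for RNA-binding proteins was up there although this median lies below that of all genes (-0.25).

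Frizzled receptors and Wnt ligands had a median of 0.11 with 18 of 28 above genes of like signal (camera's adjusted p = 0.0694 after quantile normalization and 0.605 with the deposited values). The 363 microRNA precursor genes on the array had a median of 0.02, with 56 that rose and 48 that fell, or 94 and 81 with the block (camera 0.782 and 0.605). Kinesin genes had a median of -0.06 (0.129 and 0.359) and collagen genes of 0.04 (0.549 and 0.0124). Camera's direction for collagens with the deposited values was down, but their median of -0.24 there was not below that of all genes (-0.25), 22 of 36 lay above genes of like signal, and the call was lost with the block (adjusted p = 0.0625).

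Several genes dimmer than the median lay far from those of like signal, and were chosen after their values were seen. Krtap7-1, a hair keratin-associated protein gene, changed by 1.57 and A1cf by 1.16. Emp1, an epithelial membrane protein gene, changed by 1.14, from 6.85 ± 0.240 to 7.68 ± 0.473 in the deposited values (SD, n = 3 each). The interferon-induced gene Oas1a changed by -1.08 and the natriuretic peptide receptor gene Npr3 by -0.94. The microglial receptor gene Cx3cr1 changed by 0.99, with 0.97, 0.81 and 1.17 in the 3 experiments. Olfactory and vomeronasal receptor genes, which hippocampal neurons are not known to use, changed by -1.30 to 1.41, at distances of -4.14 to 3.79 robust SDs. All of the changes named here but that of Krtap7-1 lie within the receptors' range, and so do the distances of Oas1a (-4.11) and Cx3cr1 (3.69).

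Activity-regulated genes lay above genes of like signal in 24 of 29 cases, with Dusp1 at 0.49, Fos at 0.47 and Nr4a1 at 0.43, while Plk2 fell by 0.30 and Dusp4 at 0.57 did not pass (adjusted p = 0.0816, and 0.00566 with the block). Their median lay at percentile 99.98 of 10000 random lists matched on signal, beyond what an offset that depends on signal alone would give if genes varied independently. The list was chosen for its result in these data, and random lists leave out correlation between genes. The lowest of the 3 experiments' medians was 0.14, so the list lay above genes of like signal in each. Arrays of a group share values, so the experiments are not independent here. Microglia markers, 15 of 20 above genes of like signal, lay at percentile 99.56 and fibroblast and meningeal markers, 11 of 15 above, at 97.47, so the list is not alone in this. The list's call in camera was lost with an estimated correlation (adjusted p = 0.616, and 0.937 after quantile normalization). An effect of the loss of Ncoa3 was not tested apart from the groups' processing runs and cultures, and all of these stay open.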
